A study of Oryza sativa with 15 samples.

How the data were processed

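RNA was extracted from whole rice shoots with an RNeasy kit and made into stranded NEBNext mRNA libraries, per the labels' protocols, 15 libraries in 5 groups of 3. Groups and replicate numbers came from the sample titles. The deposited values are read counts per gene, whole numbers that were not normalized. Reads were trimmed with Trimmomatic, aligned with HISAT2 and counted with featureCounts, per the submitters' processing notes, which give no versions. The genome build and the strand setting of the counting are not given in the sources used here. Without a stated strand setting, reads of overlapping and antisense genes may be mixed, and reads of close paralogs may be shared. Gene identifiers carry the suffix .MSUv7.0.

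The table held 24073 genes, of which 1205 had no count in any library. No row lacked a gene and no column of per-sample values was left unmapped. TMM scaling factors were 1.059 to 1.318 in the wet control, 0.999 to 1.11 in mild drought, 1.036 to 1.149 in severe drought, 0.622 to 0.706 after 30 min of heat and 1.066 to 1.131 after 60 min. A value of 3 counts, used as the floor, was 0.0385 to 0.0606 CPM per library by unscaled totals, without TMM factors. Bounds on genes with 0 counts set 3 counts over the group, and ratios with 1 to 3 counts have 95% exact binomial intervals. Both cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates of a group were compared before averaging: a chi-square per gene of 32.4 to 512.5 between pairs showed no library deposited more than once within a group. Libraries of different groups were not compared this way.

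Counts were tested in R 4.3.3 with edgeR 4.0.16 after filterByExpr (minimum count 10, minimum total 15), which kept 20462 genes. TMM factors and a quasi-likelihood model with robust dispersion, 1 mean per group over all 15 libraries, gave log2 fold changes, F-tests and Benjamini-Hochberg adjusted p, with 0.05 as the threshold. The SE of a log2 fold change is its size divided by the square root of F. Means ± SD are of TMM-scaled CPM over 3 libraries, and other ± values are SE. Gene lists were tested against the other genes with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over 102 tests, and again with an estimated correlation. In splits that mixed the groups of a comparison, the preset correlation also passed lists, so these calls carry that limit. Members past the threshold were counted over all genes tested and adjusted over the list alone.

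The tests, alternatives, gene lists and the rule for naming genes were chosen before the data were examined. The rule named the 6 genes with the largest rise and the 6 with the largest fall against the wet control (3 each between other groups), past the threshold, with at least 5 CPM in the higher group and no overlap of samples. It also named up to 3 members per list past the threshold, or else the member with the smallest p. The 18 lists covered heat shock proteins and chaperones, heat shock factors, endoplasmic reticulum folding, ABA, LEA proteins with dehydrins and osmoprotection, drought and cold transcription factors, photosynthesis, the clock, aquaporins, cell division, expansins, nitrogen, phosphate, jasmonate with defence, antioxidant enzymes, and root, seed and shoot meristem markers. Of 304 fixed loci 291 were in the table. The reference used for names, assembly ASM3414082v1, pairs other identifiers with symbols, so each listed name was checked by whether its symbol lies within 1000 kb of the locus's expected place. A symbol was found on the same chromosome for 209 fixed loci, all within that limit, so the distance itself removed none. Of these, 202 were in the table and were used. The 89 other fixed loci in the table had no matching symbol in the reference. By chance 7.1% of other named genes fall within that limit, and the check cannot separate tandem neighbours such as small heat shock protein, RAB16, EXPB, TIFY11, DREB1 and NAS genes. For 10 names an alias was chosen after the reference was seen.

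Alternatives were RLE size factors, no filter, DESeq2 1.42.0, the 2 compared groups alone, a replicate block, a further 2-fold limit, and each library left out in turn. For lists they were an estimated correlation and fry. Whether replicate numbers pair samples was checked by the correlation of deviations from the group means over genes. Of 10 pairs of groups, 1 had every same-numbered pair over 0.1: 30 and 60 min of heat, with 0.21 to 0.45 for the 3 pairs and -0.42 to 0.27 for the 6 others. A pairing there is read from these values alone, since the labels give only the numbers, and 1 of 10 pairs of groups could pass by chance. Scaling by total counts only, 1 surrogate variable (sva 3.50.0), all fixed loci in the lists, an estimated correlation with a library left out and a list of iron genes were chosen after seeing the data. The methods were tested on simulated counts with 200 changed genes. For severe drought against the wet control (20181 genes) 19.6% of 2-fold and 75.9% of 4-fold changes were recovered, with 2 unchanged genes among 102 past the threshold. For severe against mild drought (19833 genes) the shares were 22.8% and 75.9%, and for 30 min of heat (20196 genes) 25% and 74.1%. Genes were drawn independently, with 1 spread per gene for all groups. Differences that many genes share between libraries of 1 group were left out, so recovery and false calls may differ in the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.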

Results

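Messenger RNA was sequenced from whole shoots of rice (Oryza sativa, cultivar Nipponbare, a japonica variety) that differed in soil water or in exposure to heat. Seedlings were germinated for 3 days, set 7 to a pot and grown for 10 days under 12 h of light, at 30 °C in the light, 27 °C in the dark and 90% humidity. Soil held 3 g of water per g in the wet control, 1.5 g per g in mild drought and 1.25 g per g in severe drought. For heat, wet pots stood at 40 °C for the last 30 or 60 min, and shoots of every group were taken 6 h after dawn. Each of the 5 groups had 3 samples, 15 in all. Total counts per library were 60453774 to 68226451 in the wet control, 49479059 to 67738318 in mild drought and 52596199 to 60320309 in severe drought. They were 67857233 to 77969214 after 30 min of heat and 58426465 to 76678737 after 60 min. Of 24073 genes in the table, 1205 had no count in any library and 20462 passed the filter on low counts. The labels do not say that samples of a group came from separate pots, so p-values measure the spread between samples, which may be technical in part. That spread was estimated over all 15 libraries in 1 model, so drought p-values also rest on the spread of the heat groups. Between replicates the chi-square per gene was 166.3 to 512.5 in the wet control, 49.9 to 310.9 in mild and 70.6 to 181.3 in severe drought. It was 32.4 to 151.1 after 30 min and 37.2 to 80.5 after 60 min of heat.

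The first principal component of log2 CPM (counts scaled to a common library size) held 44.1% of the variance and set both heat groups apart from the wet and drought groups, and the second held 21.3%. Libraries of 1 group also differed among themselves along an axis that held 45.5% of the variance within groups. Wet control replicate 3, mild drought replicate 3, severe drought replicate 2 and replicate 1 of each heat time lay at its high end. All 9 expansin genes tested, which encode proteins that loosen cell walls, were higher towards that end, with a median of 0.61 log2 per SD of the axis, as were 12 of 15 heat shock protein genes (median 0.29) and 9 of 12 cell division genes (median 0.26). All 8 clock genes tested were lower towards it (median -0.16). Scaling libraries by total counts only, in place of TMM factors, moved the median log2 fold change of all genes by -0.17 in mild drought and -0.15 in severe drought. The shift was -0.88 after 30 min and -0.12 after 60 min of heat, and 0.76 between the heat times.

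**Figure D1:**
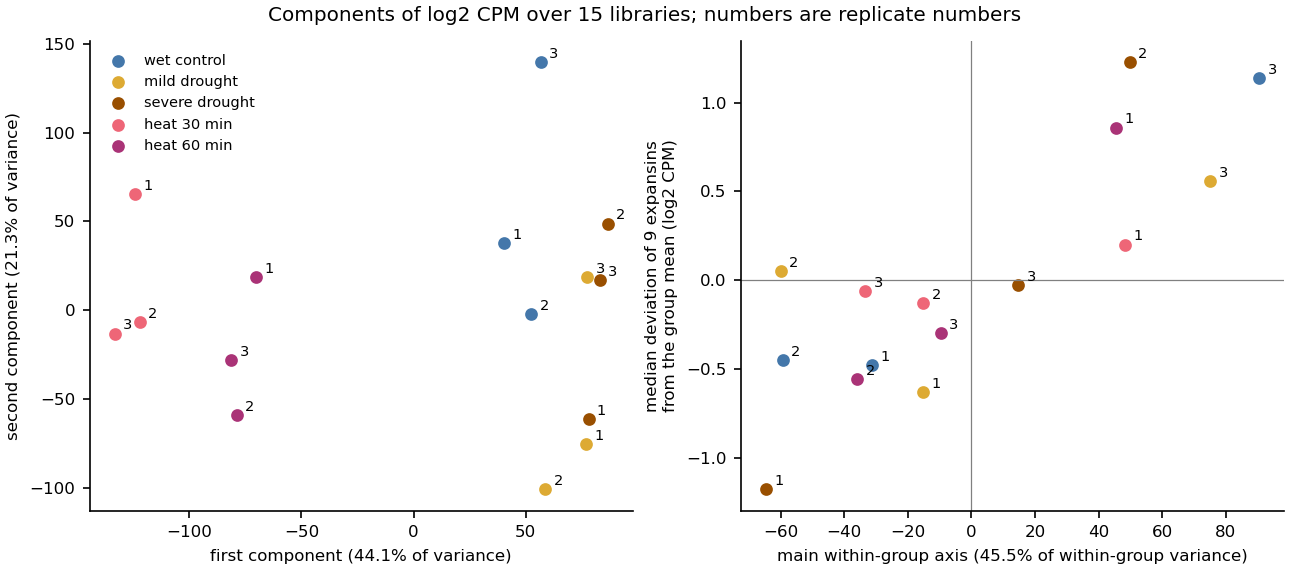
Left, scores of the 15 libraries on the first (x) and second (y) principal component of log2 CPM, coloured by group and marked with the replicate number. Right, score on the main within-group axis (x) against the median deviation of 9 expansin genes from their group mean in log2 CPM (y), where wet control replicate 3 has a score of 90.5 and a deviation of 1.14.

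Mild drought was compared with the wet control to ask which transcripts differ in shoots grown in drier soil. In mild drought, 186 genes were higher and 108 lower out of 20462 tested (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, as for every adjusted p below unless another test is named). The genes that fell furthest were NAS2 and NAS1, neighbouring genes for nicotianamine synthase, an enzyme of the route to iron-chelating phytosiderophores. NAS2 had 31.7 ± 36.5 CPM (SD, n = 3) in the wet control and 0 counts in the mild drought libraries, at least 2000-fold lower (adjusted p = 0.012, edgeR). The bound was 697 without wet control replicate 3 and 1220 and 1290 without mild drought replicates 2 and 3, which lowers the depth behind it. NAS1 had 33.6 ± 32.7 CPM against 2 counts in all, a ratio of 3170 (95% counting interval 878 to 26200). That ratio was 1480 without wet control replicate 3 and 1940 without mild drought replicate 2, and NAS1 was at least 1360-fold lower without mild drought replicate 3. NAS3, of the same family, went the other way, from 1.38 ± 0.704 to 14.1 ± 3.7 CPM (log2 fold change 3.35 ± 0.69 SE, adjusted p = 0.035, edgeR). These 3 names were matched to their loci only after their values were seen, and reads may be shared between NAS1 and NAS2. Among genes without a name in the reference, LOC_Os05g11320.MSUv7.0 rose by 4.45 ± 0.78 on the log2 scale and LOC_Os01g10400.MSUv7.0 rose by 3.03 ± 0.49, to 5690 ± 1720 CPM. LOC_Os06g19110.MSUv7.0 changed by -9.84 ± 1.39 and LOC_Os06g19095.MSUv7.0 by -8.22 ± 1.11.

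Of the 17 tested genes of abscisic acid (ABA) metabolism and signalling, the drought hormone, 4 rose and 0 fell in mild drought, and 7 rose and 1 fell when adjusted over the list alone. Among them were PP2C30 (log2 fold change 2.50 ± 0.39 SE), PP2C08 (1.81 ± 0.29) and PP2C68 (1.97 ± 0.42), members of the PP2C family of protein phosphatases that dampen ABA signalling. The ABA list had a median of 0.48 and was higher than the other genes (camera with a preset correlation, adjusted p = 1.1e-06), with an adjusted p = 0.084 with an estimated correlation. Of 12 aquaporin genes, which encode water channels, 2 rose and 0 fell, and 3 rose when adjusted over the list alone. TIP1;2, a channel of the vacuole membrane, went from 256 ± 37.2 to 866 ± 129 CPM (1.76 ± 0.21, adjusted p = 0.0048, edgeR), and PIP2;2 of the plasma membrane rose by 0.96 ± 0.18. The aquaporin list passed the camera test upwards (median 0.09, and -0.08 with libraries scaled by total counts only; adjusted p = 0.017, and adjusted p = 0.35 with an estimated correlation). The homeobox gene HOX22 rose by 1.01 ± 0.18, 1 of 11 drought and cold transcription factors past the threshold. TPP2, a trehalose phosphate phosphatase in the list of LEA proteins, dehydrins and osmoprotection, changed by -2.10 ± 0.32. The glutamate dehydrogenase gene GDH2 changed by -1.57 ± 0.25, and TIFY11A, a jasmonate repressor, by -3.61 ± 0.75.

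Lists with no member past the threshold in mild drought included 12 cell division genes (median -1.41, camera adjusted p = 0.017, and adjusted p = 0.37 with an estimated correlation). Others were 9 expansins (median -1.10, adjusted p = 0.035, and adjusted p = 0.63 with an estimated correlation) and 8 clock genes (median 0.27, and 0.12 with total counts only; adjusted p = 0.049, and adjusted p = 0.65 with an estimated correlation). Expansins, heat shock protein and cell division genes were also higher towards the high end of the within-group axis, on which wet control replicate 3 stood highest. In that library the median deviation from the wet mean was 1.14 log2 CPM for expansins and -0.06 for cell division genes. Wet control replicate 2 was the highest wet library for 9 of the 12 cell division genes. Adjusted over the list alone, 1 cell division gene was higher and 1 lower, 0 expansins were past the threshold, and 2 clock genes were higher. The clock list gave an adjusted p = 0.29 without wet control replicate 3, 0.20 without mild drought replicate 1 and 0.079 without mild drought replicate 2 (0.19 with all fixed loci, camera), and the expansin list gave 0.27, 0.11 and 0.066 (0.09 with total counts only). The cell division list gave an adjusted p = 0.16 without wet control replicate 2, and the aquaporin list 0.087 without wet control replicate 1 and 0.12 without mild drought replicate 3. The count also moved with single libraries: 30 genes were past the threshold without mild drought replicate 1, 74 without replicate 2 and 1302 without replicate 3, and 141, 932 and 59 without wet control replicates 1, 2 and 3. The majority turned in 2 of these, with 498 higher and 804 lower without mild drought replicate 3 and 399 and 533 without wet control replicate 2, and DESeq2 gave 1057 and 1233. Of the 21 named genes past the threshold, 4 stayed past it whichever library was left out (NAS1, TIP1;2 and 2 genes without a name). Scaling by total counts only gave 99 higher and 123 lower genes, and with these 2 groups alone in the model 0 genes were past the threshold (edgeR).

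Severe drought was compared with the wet control in the same way, and 335 genes were higher and 215 lower. NAS1 fell from 33.6 ± 32.7 CPM to 0 counts, at least 2010-fold lower (adjusted p = 0.0025, edgeR; 937 without wet control replicate 3 and 1250 without severe drought replicate 2), and NAS2 fell by 10.4 ± 1.49 on the log2 scale. NAS2 had 4 counts in severe drought, all in replicate 2, and changed by -8.92 without wet control replicate 3. NAS3 rose to 21 ± 9.09 CPM (3.93 ± 0.70, adjusted p = 0.011, edgeR). LOC_Os06g19110.MSUv7.0 had 39.5 ± 24.4 CPM in the wet control and 0 counts in severe drought, at least 2360-fold lower (1470 without severe drought replicate 2), and LOC_Os12g18410.MSUv7.0 changed by -13.18 ± 1.85 from 326 ± 190 CPM. LOC_Os05g11320.MSUv7.0 (4.64 ± 0.79) and LOC_Os01g10400.MSUv7.0 (3.42 ± 0.50, to 7430 ± 2370 CPM) rose as in mild drought.

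In severe drought 8 of the 17 ABA genes rose and 0 fell, and 10 rose and 1 fell when adjusted over the list alone. PP2C30 went from 1.23 ± 0.615 to 12 ± 5.6 CPM (3.28 ± 0.40, adjusted p = 0.0018, edgeR), PP2C68 rose by 2.95 ± 0.43 and PP2C49 by 2.45 ± 0.48. The ABA list had a median of 0.98 (camera adjusted p = 2.8e-15) and passed with an estimated correlation too (adjusted p = 0.014). Severe drought replicate 2, at the high end of the within-group axis, was the highest severe library for 12 of these 17 genes, with 23.8 CPM of PP2C49 against 4.68 and 11.1, and the list passed the camera test without it too. Of the 12 aquaporins 3 rose and 0 fell, also when adjusted over the list alone: TIP1;2 (1.96 ± 0.21, adjusted p = 0.00089, edgeR), PIP2;2 (0.99 ± 0.18) and PIP1;1 (0.86 ± 0.16). The aquaporin test pointed up (adjusted p = 0.034, and adjusted p = 0.40 with an estimated correlation) while the list median was -0.07 (-0.21 with total counts only) and its mean 0.15. Of 21 heat shock factor genes 2 rose, HSFC2B (3.74 ± 0.61) and HSFC2A (1.82 ± 0.39), and 3 rose when adjusted over the list alone. The factor list had a median of 0.11 (-0.03 with total counts only; camera adjusted p = 0.033, and adjusted p = 0.12 with an estimated correlation). HOX22 rose by 1.41 ± 0.18, 1 of 11 in its list, and APX1, an ascorbate peroxidase, by 2.07 ± 0.45, 1 of 11 antioxidant genes (2 when adjusted over the list alone).

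Genes of other lists fell in severe drought. In the LEA, dehydrin and osmoprotection list 3 of 13 genes fell and 0 rose (5 fell and 1 rose when adjusted over the list alone). Their median was -0.59 (camera adjusted p = 0.0037, and adjusted p = 0.26 with an estimated correlation). The LEA protein gene Emp1 had 9.66 ± 7.96 CPM in the wet control and 0 counts in severe drought, at least 574-fold lower (317 without wet control replicate 2 and 357 without severe drought replicate 2). Emp1 had 0 counts in mild drought too, where it was not past the threshold. Its call in severe drought was lost in all 6 fits with a library left out and with the replicate block (adjusted p = 0.081, edgeR). LEA3-2 changed by -5.67 ± 1.02, and TPP2 by -2.25 ± 0.32. In the jasmonate and defence list, 1 of 19 genes fell, TIFY11A (-4.51 ± 0.79), and 5 fell when adjusted over the list alone. The list median was -1.2 (camera adjusted p = 0.00049, and adjusted p = 0.37 with an estimated correlation). Wet control replicate 1 was the highest wet library for 13 of these 19 genes, with 728 CPM of PBZ1, a defence gene, against 167 and 35.3 in replicates 2 and 3, and without it the list gave an adjusted p = 0.02. The 12 cell division genes had a median of -1.48 with 0 past the threshold (1 higher when adjusted over the list alone; camera adjusted p = 0.022, and adjusted p = 0.40 with an estimated correlation). GDH2 changed by -1.21 ± 0.25, 1 of 9 nitrogen genes, and the clock gene PCL1 by -2.89 ± 0.62, 1 of 8. The heat shock factor list gave a camera adjusted p = 0.065 without wet control replicate 3 and 0.072 without severe drought replicate 2, and the cell division list 0.17 without wet control replicate 2. The aquaporin list gave an adjusted p = 0.18 without wet control replicate 1 and 0.095 and 0.075 without severe drought replicates 2 and 3, and the LEA list 0.055 with all fixed loci. Leaving out a library gave 290 genes past the threshold without wet control replicate 1 and 312, 354 and 215 without severe drought replicates 1, 2 and 3. Scaling by total counts only gave 200 higher and 257 lower, 212 were higher and 220 lower without wet control replicate 3, and 13 and 19 with only those 2 groups. Of 27 named genes past the threshold 17 stayed past it whichever library was left out. Emp1, HSFC2A, PP2C49, LEA3-2, PCL1, PIP2;2, PIP1;1, GDH2, TIFY11A and APX1 did not, with adjusted p up to 0.13.

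The photosynthesis list kept 3 genes after the name check, and 0 changed in either drought (medians 0.37 and 0.39), with CAB1R, a light-harvesting protein gene, at 14900 ± 1440 CPM in severe drought and 11400 ± 1660 CPM in the wet control. With all 28 fixed photosynthesis loci in the file, chosen as an alternative after seeing the data, the list was higher in mild (camera adjusted p = 3.5e-08) and severe drought (adjusted p = 3.6e-08), with adjusted p = 0.48 for both with an estimated correlation. No name-checked member of the heat shock protein, endoplasmic reticulum folding, phosphate starvation, root marker or seed marker lists changed in either drought over all genes tested. Adjusted over the list alone, 3 heat shock protein genes were higher and 3 lower in severe drought, 1 and 1 in mild drought, and 1 phosphate starvation gene was higher in severe drought. With all fixed loci, 1 of 26 heat shock protein loci was higher over all genes tested in mild drought and 1 in severe drought. Of the 28 photosynthesis loci 1 was higher in mild and 2 in severe drought, and 0 were lower. Without wet control replicate 3, which stood highest on the within-group axis, the heat shock protein list passed the camera test upwards in mild (adjusted p = 0.00013, and adjusted p = 0.24 with an estimated correlation) and severe drought (adjusted p = 1e-05, and adjusted p = 0.17 with an estimated correlation). With all libraries that test pointed down in mild and up in severe drought, past the threshold in neither. None of the 4 shoot meristem marker genes had enough counts to be tested. Among the root markers, LSI1, a silicon channel of roots, had 22.4 ± 7.08 CPM in severe drought and 16.2 ± 4.07 in the wet control.

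Mild and severe drought were compared to ask whether the depth of drying mattered, and 0 genes were past the threshold (569 at an unadjusted p under 0.05, and 43 by DESeq2, of which 18 were higher and 25 lower). The log2 fold changes of severe over mild drought with the smallest p in their lists were -2.94 ± 0.62 for PCL1 (adjusted p = 0.81, edgeR), 2.54 ± 0.58 for HSFC2B and 1.85 ± 0.45 for NCED3, an enzyme of ABA synthesis. The dehydrin gene RAB16D had 48 counts over the mild and 2 over the severe drought libraries, a ratio of 22.8 (95% counting interval 5.97 to 193). That ratio was 12.7 without mild drought replicate 1, and RAB16D was at least 9.43-fold lower without severe drought replicate 2. As a list, the ABA genes stood higher in severe than in mild drought (median 0.48, 13 of 17 above 0, camera adjusted p = 5.2e-08, and adjusted p = 0.083 with an estimated correlation). It passed the camera test also without severe drought replicate 2, the highest severe library for 12 of the 17. The LEA list was lower (median -0.51, adjusted p = 2.5e-05, and adjusted p = 0.084 with an estimated correlation). Mild drought replicate 1 was the highest mild library for 7 of its 13 genes, with 10.7 CPM of RAB21 against 0.186 and 0.336 and 12.1 CPM of LEA3-1 against 1.64 and 0.598, and without it the list gave an adjusted p = 0.0057. Also lower were the jasmonate list (median -0.54, adjusted p = 5.8e-05, and adjusted p = 0.29 with an estimated correlation), the clock list (-0.11, adjusted p = 0.0046, and adjusted p = 0.48 with an estimated correlation) and the folding list (-0.29, adjusted p = 0.046, and adjusted p = 0.56 with an estimated correlation). The folding list gave an adjusted p = 0.72 without mild drought replicate 2, 0.16 and 0.11 without severe drought replicates 2 and 3, and 0.067 with total counts only. The clock list gave an adjusted p = 0.15 without mild drought replicate 1 and 0.086 without severe drought replicate 3, and the jasmonate list 0.079 without mild drought replicate 3 and 0.065 without severe drought replicate 1. Adjusted over the list alone, 3 ABA genes and 1 heat shock factor gene were higher and 4 LEA genes and 1 clock gene lower. Of the genes past the threshold in each drought, 238 changed the same way in both and 0 in opposite ways, against an overlap of 3 higher and 1 lower for independent lists. It was at most 1 gene in 20 simulations of unchanged groups against the same wet libraries, which had at most 2 genes past the threshold in a comparison and so little to share. Fold changes correlated across genes at 0.73 with a covariance of 0.81, against 0.5 and 0.15 in those simulations, a difference in covariance of 0.66. The simulations gave each gene 1 spread for all groups and drew genes independently, while wet replicates differed more than heat replicates. They may understate what the shared wet libraries add, so 0.66 need not be the part beyond those libraries. Part of the overlap may still come from the shared controls, since 3 libraries are too few to give each comparison its own.

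After 30 min at 40 °C, 3946 genes were higher and 4007 lower than in the wet control. All 15 tested heat shock protein and chaperone genes rose, with a median log2 fold change of 11.22 (camera adjusted p = 3.4e-45, and adjusted p = 6e-04 with an estimated correlation). All 15 also rose when adjusted over the list alone. HSP23.2, a small heat shock protein, went from 0.511 ± 0.77 to 10000 ± 1120 CPM (14.26 ± 1.27, adjusted p = 1.7e-06, edgeR), HSP26.7 to 11000 ± 717 and HSP21.9 to 2860 ± 302. Wet control replicate 3 was the highest wet library for 13 of the 15 genes and held most of the low baseline, with 1.4 CPM of HSP23.2 against 0.0497 and 0.083. Without it the fitted log2 fold change was 17.17 for HSP23.2 and 15.32 for HSFA2A, a heat shock factor. Of 21 heat shock factors, the transcription factors of this response, 15 rose and 1 fell (16 and 1 when adjusted over the list alone). Their median was 2.64 (camera adjusted p = 3.9e-17, and adjusted p = 0.00043 with an estimated correlation). HSFA2A went from 0.568 ± 0.752 to 5930 ± 617 CPM (13.35 ± 1.27), HSFA2C from 12.5 ± 2.44 to 3070 ± 140 and HSFB2B from 2.4 ± 0.849 to 499 ± 43.8. All 7 tested genes of protein folding in the endoplasmic reticulum rose, also when adjusted over the list alone, among them PDIL2-3, a disulfide isomerase, from 30.6 ± 7.02 to 922 ± 202 CPM, ERDJ3B by 4.91 ± 0.38 and BIP4 by 5.07 ± 1.70 (2.98 without 30 min replicate 1). Their median was 4.86 (camera adjusted p = 1.4e-09, and adjusted p = 0.083 with an estimated correlation). BIP4 lay near the floor, with 4 counts over the wet libraries and 0.65 ± 0.858 CPM at 30 min. Among genes without a name, LOC_Os07g47840.MSUv7.0 rose from 0.0583 ± 0.101 CPM, 13 counts that were all in wet control replicate 3, to 1880 ± 259 CPM and LOC_Os04g01740.MSUv7.0 from 1.47 ± 2.35 to 20400 ± 708. LOC_Os04g08828.MSUv7.0 fell by 5.3 ± 0.57 and LOC_Os09g04384.MSUv7.0 fell by 5.17 ± 0.47 on the log2 scale.

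**Figure D2:**
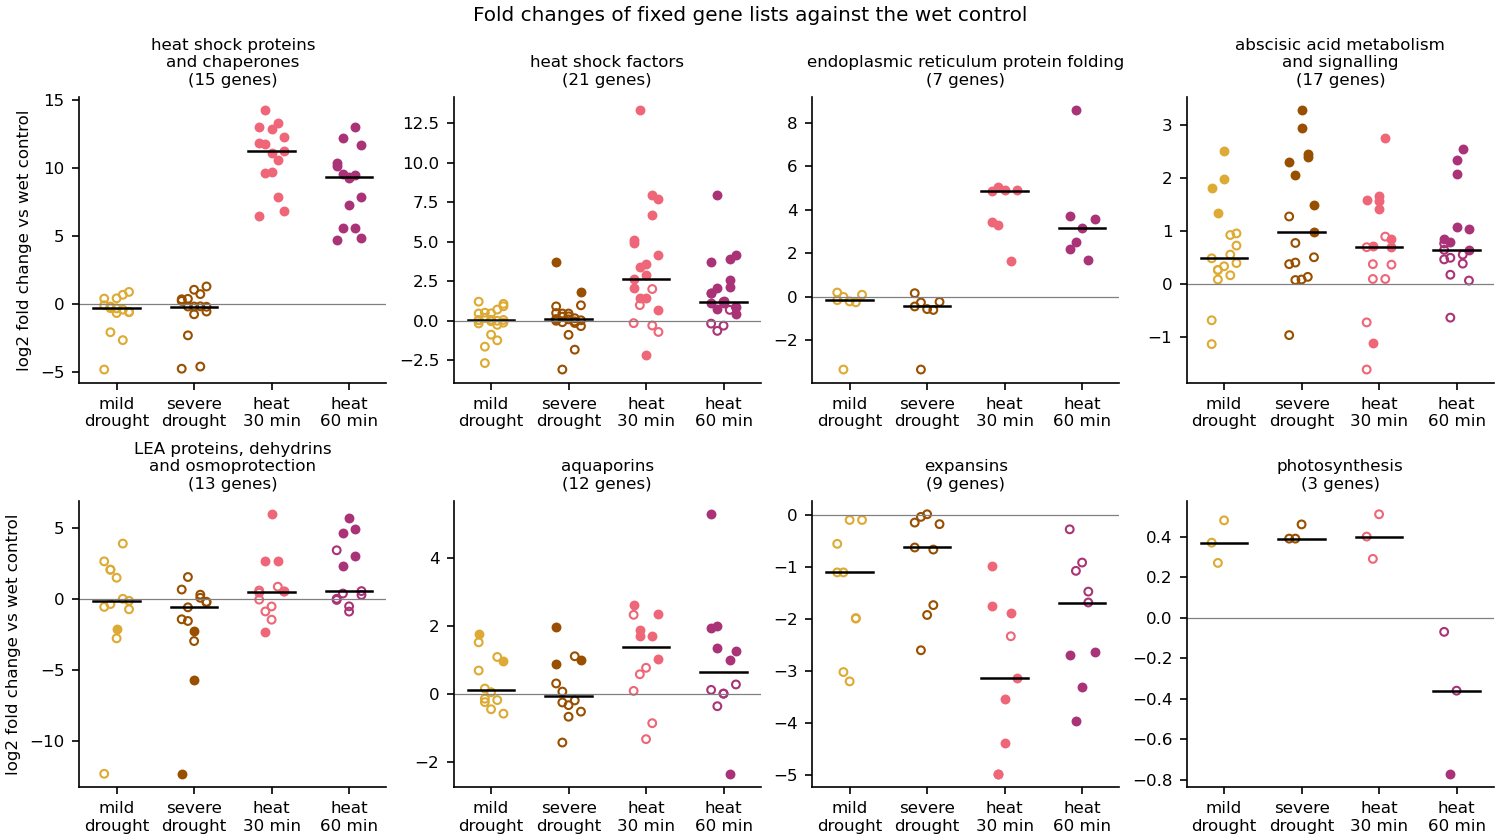
Log2 fold change of each tested member of 8 fixed lists (y) against the wet control in mild drought, severe drought, 30 min and 60 min of heat (x). Filled points passed the edgeR threshold, open points did not, and bars are list medians: 11.22 and 9.36 for the 15 heat shock protein genes under heat, 0.48 and 0.98 for the 17 ABA genes in mild and severe drought.

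Scaling decided part of the other lists at 30 min, when 335 genes at least 16-fold higher held 28.4 to 32% of all counts, against 0.5 to 0.6% in the wet control. With total counts only, 1480 genes were higher and 12475 lower. Of the 17 ABA genes 8 rose and 1 fell, also when adjusted over the list alone, with a median of 0.69 (-0.17 with total counts only; camera adjusted p = 0.20). Among them were PP2C49 (2.75 ± 0.49), PP2C30 (1.66 ± 0.38) and ZEP1, a zeaxanthin epoxidase (1.59 ± 0.33). Of 13 LEA, dehydrin and osmoprotection genes 4 rose and 1 fell, also when adjusted over the list alone (median 0.52, and -0.39 with total counts only; adjusted p = 0.40). They included the dehydrins RAB16D (5.95 ± 0.67), RAB16C (2.68 ± 0.58) and LIP9 (2.64 ± 0.24, to 111 ± 4.55 CPM). Of 11 drought and cold transcription factors 6 rose and 1 fell, also when adjusted over the list alone (median 0.76, and -0.08 with total counts only; adjusted p = 0.14). They included HOX24 (3.23 ± 0.74), DREB1C (2.89 ± 0.84) and DREB1A (1.84 ± 0.29). Of 12 aquaporins 6 rose and 0 fell (6 and 1 when adjusted over the list alone). The list median was 1.36 (0.48 with total counts only; camera adjusted p = 0.021, and adjusted p = 0.37 with an estimated correlation). TIP1;2 reached 1580 ± 325 CPM, TIP1;1 3130 ± 505 from 619 ± 244, and PIP1;2 1680 ± 127 from 464 ± 75. Of 11 antioxidant genes 5 rose and 1 fell, also when adjusted over the list alone (median 0.59, and -0.29 with total counts only; adjusted p = 0.039, and adjusted p = 0.26 with an estimated correlation). APX2 (2.29 ± 0.14), APX1 (1.94 ± 0.44) and SODCC2 (1.48 ± 0.18) were among those that rose. The antioxidant list gave an adjusted p = 0.10 with total counts only and 0.068 with all fixed loci.

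Expansins fell at 30 min: 8 of 9 were lower and 0 higher (9 lower when adjusted over the list alone). The median was -3.14 (camera adjusted p = 0.033, and adjusted p = 0.63 with an estimated correlation). EXPA2 went from 27.9 ± 21.1 to 0.88 ± 0.471 CPM (-4.98 ± 0.99), EXPB4 changed by -4.98 ± 1.27 and EXPB6 by -4.38 ± 1.16. Without wet control replicate 3 EXPB4 was at -2.32 and EXPB6 at -2.7, neither past the threshold. Expansins were also higher towards the high end of the within-group axis, where wet control replicate 3 lay, and without that library the list test gave an adjusted p = 0.054 (0.34 with total counts only). NIA1, a nitrate reductase, went from 110 ± 61.5 to 4.23 ± 2.15 CPM (-4.71 ± 0.67). It fell with GS1;1, a cytosolic glutamine synthetase, from 363 ± 52 to 123 ± 6.27 CPM, 2 of 9 nitrogen genes in all. In the clock list 3 of 8 genes rose and 1 fell (median 0.33, and -0.53 with total counts only). PCL1, of the evening complex, went from 0.66 ± 0.495 to 23.4 ± 4.03 CPM (5.14 ± 0.57), ELF3-1 rose by 1.05 ± 0.33, and PRR1 changed by -1.3 ± 0.19. Of 12 cell division genes 1 rose and 1 fell: MCM7, a subunit of the replicative helicase, from 0.533 ± 0.127 to 19.1 ± 3.35 CPM (5.16 ± 0.78), and MCM2 by -1.33 ± 0.27. Of 8 phosphate starvation genes 2 rose, SPX1 (2.6 ± 0.23) and PT4 (1.27 ± 0.23). Of 19 jasmonate and defence genes 1 rose, TIFY10A (0.75 ± 0.21, and -0.13 with total counts only), and 1 fell, AOC (-1.3 ± 0.28). None of the 3 photosynthesis genes left after the name check changed, and no root or seed marker did. Of all 28 fixed photosynthesis loci 6 rose and 0 fell, against 0 and 20 with total counts only (camera adjusted p = 0.20). Of 46 named genes past the threshold 39 stayed past it whichever library was left out, and BIP4, DREB1C, ELF3-1, EXPB4, EXPB6, TIFY10A and 1 gene without a name did not, with adjusted p up to 0.19. With total counts only, BIP4, PP2C30, ELF3-1, PT4 and APX1 were no longer past it.

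After 60 min at 40 °C, 3311 genes were higher and 3235 lower than in the wet control (2582 and 3813 with total counts only). DESeq2 gave 3731 higher and 4124 lower, and 2857 and 3437 were found without wet control replicate 2. The 15 heat shock protein genes all rose again (median 9.36, camera adjusted p = 6.9e-56, and adjusted p = 0.00043 with an estimated correlation; 15 when adjusted over the list alone). They were led by HSP26.7 at 8930 ± 683 CPM (12.99 ± 1.38, adjusted p = 1.7e-05, edgeR), HSP23.2 at 2450 ± 313 and HSP16.9A at 3880 ± 647. Without wet control replicate 3 the fitted log2 fold changes of these 3 genes were 16.28, 15.15 and 15.35. Heat shock factors rose in 15 of 21 cases and 0 fell (16 and 0 when adjusted over the list alone; median 1.19, camera adjusted p = 9.9e-12, and adjusted p = 6e-04 with an estimated correlation). HSFA2A stood at 140 ± 24.6 CPM, HSFA2C at 189 ± 14.8 and HSFB2B at 43.1 ± 5.73. The 7 folding genes rose (median 3.18, camera adjusted p = 6.2e-11, and adjusted p = 0.063 with an estimated correlation; 7 when adjusted over the list alone). The chaperone gene BIP1 went from 140 ± 39 to 1820 ± 524 CPM, PDIL2-3 reached 369 ± 78.3 and BIP4 rose by 8.59 ± 1.80. BIP4 started near the floor, with 4 counts over the wet libraries, and had 7.52 ± 7.45 CPM at 60 min. LOC_Os01g04360.MSUv7.0 rose by 11.13 ± 1.00 and LOC_Os01g04340.MSUv7.0 by 10.56 ± 0.75. LOC_Os08g26710.MSUv7.0 fell by 5.31 ± 0.40 and LOC_Os11g18366.MSUv7.0 fell by 5.16 ± 0.73 on the log2 scale.

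Genes of the water stress lists also rose at 60 min. Of 17 ABA genes 8 rose and 0 fell (10 and 1 when adjusted over the list alone; median 0.64, camera adjusted p = 0.019, and adjusted p = 0.40 with an estimated correlation). They included NCED3 (2.55 ± 0.46), PP2C68 (2.33 ± 0.42) and PP2C30 (2.07 ± 0.38). Of 13 LEA, dehydrin and osmoprotection genes 5 rose and 0 fell (6 and 0 when adjusted over the list alone; median 0.55, camera adjusted p = 0.023, and adjusted p = 0.40 with an estimated correlation). RAB16D rose by 5.72 ± 0.67, RAB21 by 4.95 ± 1.31, and LEA3-1 went from 1.14 ± 1.33 to 28.3 ± 20.1 CPM (4.63 ± 1.14). Of 11 drought and cold transcription factors 7 rose, also when adjusted over the list alone (median 0.95, camera adjusted p = 0.033, and adjusted p = 0.29 with an estimated correlation). They included DREB1C (2.53 ± 0.83), HOX24 (2.22 ± 0.71) and HOX22 (1.14 ± 0.18). Aquaporins rose in 6 of 12 cases and 1 fell, also when adjusted over the list alone (median 0.63, camera adjusted p = 0.041, and adjusted p = 0.40 with an estimated correlation). PIP2;3 rose by 5.28 ± 1.12 and PIP2;4 by 1.98 ± 0.53, with PIP2;7 at -2.36 ± 0.50. Without wet control replicate 1 the aquaporin test gave an adjusted p = 0.084, and without wet control replicate 3 the transcription factor test gave 0.064.

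Members of the cell division, expansin and nitrogen lists fell at 60 min, while none of these 3 lists passed its test with all libraries. With all fixed loci, an alternative chosen after seeing the data, 6 of 14 nitrogen genes fell and 0 rose. That longer list passed (median -1.01, camera adjusted p = 0.015, and adjusted p = 0.12 with an estimated correlation). With an adjusted p = 0.033 and 0.029 the expansin list did without wet control replicate 1 and without 60 min replicate 1, and with 0.037 the nitrogen list did without wet control replicate 3 (camera, and adjusted p = 0.64, 0.57 and 0.20 with an estimated correlation). Of 12 cell division genes 5 fell and 0 rose (6 and 0 when adjusted over the list alone; median -1.78, camera adjusted p = 0.079). They included MCM4 (-5.04 ± 1.34), MCM5 (-3.88 ± 1.33, with 11 counts over the 60 min libraries) and MCM3 (-3.68 ± 1.25), which had 0.654, 0.729 and 0.485 CPM in the wet control. With 1 library left out MCM5 ran from -6.43 to -3.34. Of 9 expansins 4 fell (5 when adjusted over the list alone; median -1.68, camera adjusted p = 0.079). They included EXPB4 (-3.97 ± 1.2), EXPB6 (-3.31 ± 1.09) and EXPB3 (-2.69 ± 0.65). Without wet control replicate 3, which had 105 CPM of EXPB4 against 5.94 and 6.35 in the other wet libraries, these were -1.3, -1.61 and -1.87, and EXPB4 and EXPB6 were not past the threshold. Both also missed it without 60 min replicate 2 or 3. NIA1 (-2.02 ± 0.59), GS1;1 (-1.88 ± 0.21) and the glutamate synthase gene GLT2 (-1.81 ± 0.53) were the 3 of 9 nitrogen genes that fell (3 when adjusted over the list alone; median -0.41, camera adjusted p = 0.093). The catalase gene CATA went from 971 ± 409 to 67.7 ± 4.51 CPM (-3.84 ± 0.45), while APX1 (2.22 ± 0.45) and APX2 (1.76 ± 0.13) rose, in an antioxidant list with 4 higher and 1 lower. In the clock list 1 of 8 genes rose, PCL1 (3.53 ± 0.53), and 2 fell, PRR37 (-1.17 ± 0.18) and PRR73 (-1.12 ± 0.19). Of the other lists, CAB2R (-0.77 ± 0.24, photosynthesis) and NRAMP5 (-4.10 ± 1.03, a metal transporter among the root markers) fell, SPX1 (1.07 ± 0.22) rose, and 0 of 19 jasmonate genes changed. Of all 28 fixed photosynthesis loci 5 fell and 0 rose (11 and 0 with total counts only; camera adjusted p = 0.055). Of 48 named genes past the threshold, 35 stayed past it whichever library was left out. RAB21, DREB1C, HOX24, CAB2R, MCM3, MCM4, MCM5, EXPB4, EXPB6, NIA1 and GLT2 were among the other 13, with adjusted p up to 0.30.

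**Figure D3:**
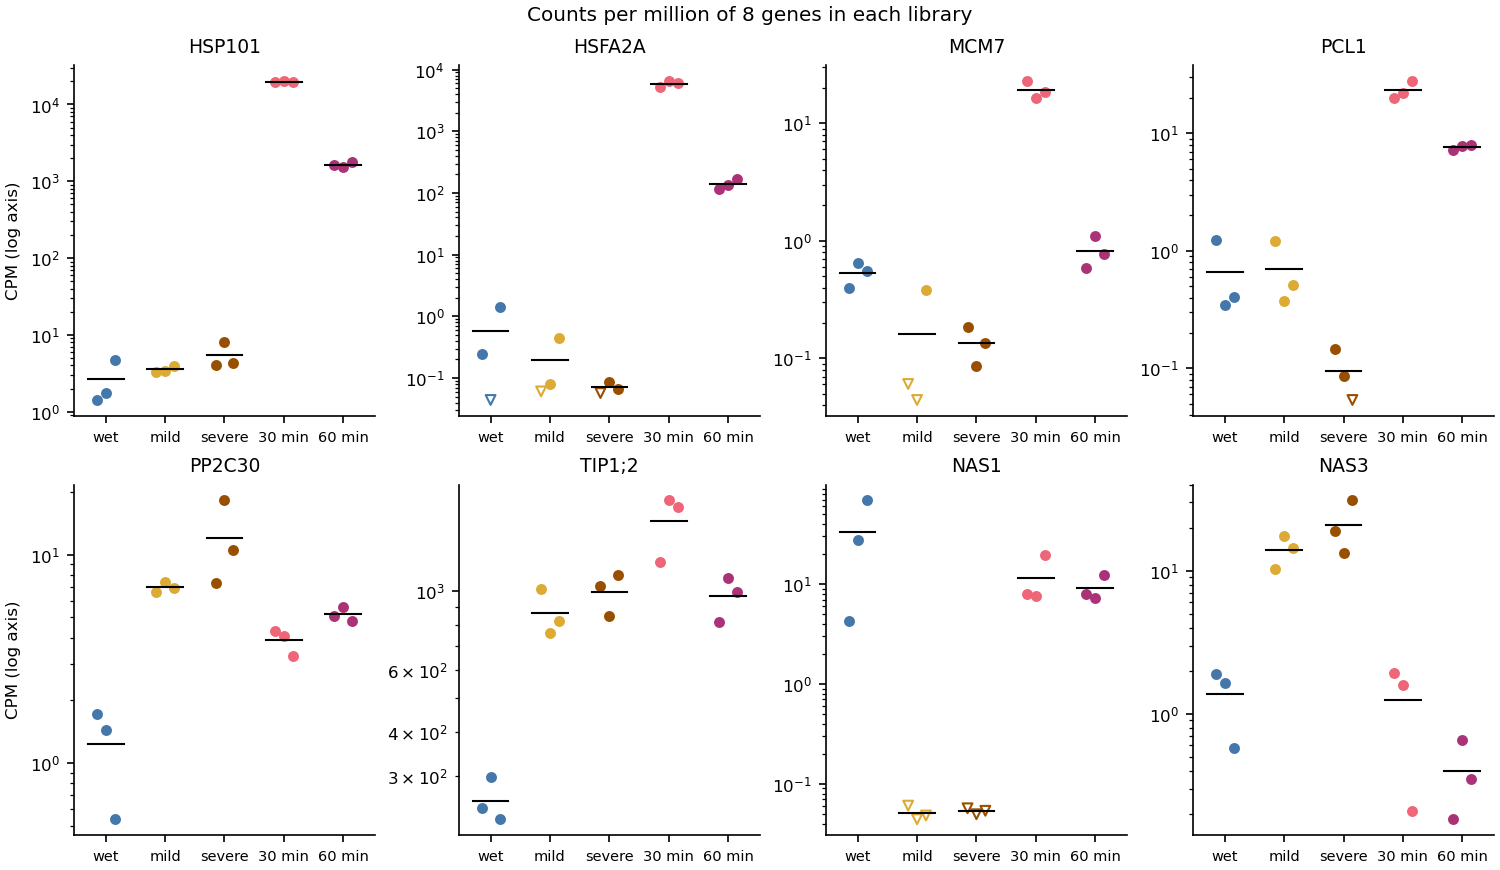
CPM on a log axis (y) of 8 genes in each library, by group (x), with bars at group means. Open triangles are libraries whose TMM-scaled CPM was under the floor, drawn at the floor and set to it in the means. The floor is 3 counts over the unscaled library total, 0.0385 to 0.0606 CPM over the 15 libraries, so a triangle does not mark exactly fewer than 3 counts. HSFA2A had a mean of 5930 CPM at 30 min and 140 CPM at 60 min, and NAS1 was at its floor in the drought libraries.

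The heat times were compared directly to ask how the response moved between them: 2121 genes were higher and 2850 lower at 60 than at 30 min (10067 and 679 with total counts only). Of the 15 heat shock protein genes 12 fell and 0 rose (13 and 0 when adjusted over the list alone; median -2.04, and -1.28 with total counts only; camera adjusted p = 2.1e-14, and adjusted p = 0.084 with an estimated correlation). HSP101, a disaggregase, went from 19900 ± 215 to 1650 ± 116 CPM (-3.60 ± 0.41), ClpB-m from 10400 ± 191 to 655 ± 81.9 and HSP18.6 from 8340 ± 1040 to 824 ± 67.1. Of 21 heat shock factors 12 fell and 2 rose, also when adjusted over the list alone (median -1.43, and -0.66 with total counts only; camera adjusted p = 1.6e-12, and adjusted p = 0.00043 with an estimated correlation). They included HSFA2A (-5.40 ± 0.92), HSFB2A (-4.10 ± 0.20) and HSFA2C (-4.02 ± 0.21). Of 7 folding genes 5 fell (median -1.16, and -0.43 with total counts only; camera adjusted p = 0.033, and adjusted p = 0.52 with an estimated correlation; 5 fell and 1 rose when adjusted over the list alone). They included ERDJ3B (-1.72 ± 0.33), PDIL2-3 (-1.32 ± 0.21) and bZIP39 (-1.26 ± 0.26). That list test gave an adjusted p = 0.088 without 30 min replicate 1 and 0.083 without 60 min replicate 2.

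Other genes were higher at 60 than at 30 min, led by LEA3-1 (5.51 ± 1.21), LOC_Os06g46740.MSUv7.0 (4.34 ± 1.00) and LOC_Os09g20220.MSUv7.0 (4.29 ± 1.04). With RAB21 (4.09 ± 1.26) and TPP1 (2.71 ± 0.52), 3 of 13 LEA list genes rose and 0 fell. EXPA2 (3.90 ± 0.95), EXPA4 (2.63 ± 0.63), NIA1 (2.68 ± 0.61), NCED3 (1.66 ± 0.45) and PRR1 (1.31 ± 0.19) were higher too. MCM7 fell by 4.54 ± 0.75, LOC_Os02g34270.MSUv7.0 fell by 6 ± 0.69 and LOC_Os07g47840.MSUv7.0 fell by 5.83 ± 0.65 on the log2 scale. CATA changed by -2.36 ± 0.42, SPX1 by -1.53 ± 0.23, CAB2R by -1.06 ± 0.24 and PP2C49 by -2.20 ± 0.48. Scaling by total counts only moved the median gene by 0.76 log2 between the heat times, so the size of these falls depends on the scaling. Of 12 cell division genes 3 fell and 1 rose (8 and 1 when adjusted over the list alone; median -1.87, and -1.13 with total counts only; camera adjusted p = 0.079, and adjusted p = 0.53 with an estimated correlation). Without 30 min replicate 3 that list gave an adjusted p = 0.047, and adjusted p = 0.48 with an estimated correlation. Of all 28 fixed photosynthesis loci 17 fell and 0 rose (26 and 0 when adjusted over the list alone, and 2 and 2 with total counts only). Their median was -0.61 (0.16 with total counts only; camera adjusted p = 1.4e-06, and adjusted p = 0.55 with an estimated correlation). Among aquaporins 6 of 12 fell and 1 rose (median -0.71, and 0.06 with total counts only). The counts fell to 3151 without 30 min replicate 2 and to 2973 and 2978 without 60 min replicates 2 and 3. Of 46 named genes past the threshold 25 stayed past it whichever library was left out, and LOC_Os09g20220.MSUv7.0, RAB21 and NCED3 were among the other 21, with adjusted p up to 0.18.

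The responses to severe drought and to 60 min of heat were compared gene by gene. The same direction was found in 192 genes past the threshold in both, 151 higher and 41 lower, and opposite directions in 91. With total counts only, 75 were higher and 67 lower in both, and 69 went in opposite directions. Independent lists of these sizes would share 54 higher and 34 lower genes, with 53 and 35 in the 2 opposite classes (25 and 48, with 37 and 32, for total counts only). Genes higher in both included TIP1;2 (1.96 in drought and 1.92 in heat), NCED3 (2.40 and 2.55), PP2C68 (2.95 and 2.33), PP2C50 (0.98 and 1.03), HOX22 (1.41 and 1.14) and APX1 (2.07 and 2.22). None of these 6 differed past the threshold between the treatments (adjusted p from 0.25 to 0.90). PP2C30, PP2C08 and HSFC2B were higher in both and higher in severe drought than in heat (differences of 1.22, 1.46 and 1.98). PCL1 went in opposite ways, with -2.89 in drought and 3.53 in heat (difference -6.41, adjusted p = 9.9e-06, edgeR). Between the treatments themselves, 3441 genes were higher in severe drought and 3761 lower than after 60 min of heat. Fold changes correlated across genes at 0.21 with a covariance of 0.26, against 0.5 and 0.15 in 20 simulations of unchanged groups with the same controls, a difference in covariance of 0.11. With the same spread for all groups, these simulations may understate what the shared wet libraries add, so 0.11 need not be the part beyond them. Genes are not independent replicates, those simulations had at most 2 genes past the threshold in a comparison and shared 0, and part of the excess over independent lists may come from the shared controls. The count of 192 moved to 127 and 117 without wet control replicates 1 and 3, 118 and 89 without severe drought replicates 1 and 3, and 123, 108 and 114 without 60 min replicates 1, 2 and 3. The 91 in opposite directions became 25 and 51 without wet control replicates 1 and 3, 41, 49 and 26 without severe drought replicates 1, 2 and 3, and 56, 39 and 37 without 60 min replicates 1, 2 and 3. The 41 lower in both ran from 12 without 60 min replicate 2 to 84 without wet control replicate 2, and the 151 higher in both from 74 without severe drought replicate 3 to 150 without wet control replicate 2.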

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

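All tests of explanations and of other splits in this part were chosen only after the result was seen. The response to heat differed between 30 and 60 min in 4971 genes by a direct test of the difference (edgeR). Opposite directions at the 2 times, each past the threshold together with their difference, were seen in 52 genes, 28 higher then lower and 24 lower then higher. By the same test 12 heat shock protein genes, 12 heat shock factor genes and 5 endoplasmic reticulum folding genes were lower at 60 than at 30 min.

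For each comparison of 3 with 3 samples there are 10 splits, too few for a share under 0.05. The real number of genes and the highest of the other splits were 294 and 130 in mild drought, 550 and 0 in severe drought, 7953 and 0 after 30 min and 6546 and 0 after 60 min of heat. They were 4971 and 0 between the heat times and 7202 and 0 between severe drought and 60 min of heat, and in each of these 6 comparisons 1 split, the real one, gave as many genes. Every other split mixes libraries of both groups, so a group difference becomes spread within groups and holds its count down. These counts therefore do not show whether the real numbers exceed chance. Between the heat times, where same-numbered samples correlated, the 3 other splits that part every same-numbered pair mixed both times and gave 0. For severe against mild drought the real split gave 0 and the highest other 3656, so all 10 gave as many. That split set severe drought replicate 1 and mild drought replicates 1 and 2 against the rest, and it follows the within-group axis. These libraries scored -64.6, -15.3 and -59.9 on the axis. Severe drought replicates 2 and 3 and mild drought replicate 3 scored 49.9, 14.7 and 75.2. The numbers of lists past the threshold, with the highest other split, were 4 and 5 in mild drought (3 splits gave as many), 6 and 5 in severe drought (1), 5 and 3 in severe against mild drought (1), 6 and 7 after 30 min (5), 7 and 9 after 60 min (4), and 3 and 6 between the heat times (7). For the genes shared by severe drought and 60 min of heat, 2 of 60 splits drawn of 840 gave 192 or more. The other of the 2 gave 4614 with the 3 libraries of 60 min of heat as controls, a split that follows a group. All 55 splits whose controls mixed groups gave 0, so this count does not show whether the shared genes exceed chance.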

How the results depend on the processing

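Total counts only, 1 surrogate variable, all fixed loci and an estimated correlation with a library left out were chosen after seeing the data, and the cause of the changes below was not tested except where named. Genes past the threshold moved by over 1.5 times in mild drought to 74 with 1 surrogate variable, 2290 with DESeq2 and 0 with only the 2 groups, and in severe drought to 901, 1811 and 32. DESeq2 called 43 in severe against mild drought. In simulated counts DESeq2 called 36 to 53 unchanged genes. Total counts only gave 13955 after 30 min of heat and 10746 between the heat times. A further 2-fold limit, by construction, gave 4762, 3500, 2356 and 4036 for 30 min, 60 min, the heat times and severe drought against 60 min. An estimated correlation left 6 of 32 list tests. Shared genes were 577 with DESeq2 and 88 with the 2-fold limit. With total counts only, TIFY10A turned to -0.13 after 30 min, and PT4 to 0.02, APX2 to 0.23 and SODCC1 to 0.33 between the heat times. Each list call that appeared only with a library left out had adjusted p = 0.17 to 0.64 with an estimated correlation. RLE factors and no filter kept every count of genes within 1.5 times.

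With 1 library left out, and fewer samples by construction, counts ranged from 30 to 1302 in mild drought, 215 to 617 in severe drought, 0 to 4 in severe against mild drought, 6305 to 7731 after 30 min, 4470 to 6294 after 60 min, 2973 to 3777 between the heat times, 5197 to 6751 in severe drought against 60 min, 30 to 33 list tests and 89 to 234 shared genes. The 4 came without mild drought replicate 2. A replicate block gave 203 in mild and 416 in severe drought, 7703 and 6281 for 30 and 60 min, 4780, 7004, 32 list tests and 153 shared genes. Between the heat times, where same-numbered samples correlated, the block ended 4 of 46 named calls (NAC6, DREB1A, PIP2;3 and CDKB2;1, adjusted p = 0.051 to 0.068) and no other named gene or list call. Elsewhere samples share only a number: over all groups 13 of 30 same-numbered pairs had deviations correlated over 0.1 (-0.46 to 0.55), and 5 of 15 samples correlated best with their own number. Among named genes, calls were lost in 12 cases with the block, 17 with the surrogate variable and 51 with only the 2 groups. Depth limits falls to the floor of 3 counts, 0.0385 to 0.0606 CPM per library by unscaled totals, below which no change was detectable.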

Other observations

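The tests in this part were chosen only after the results were seen, except the tests of counts taken by strongly induced genes and of a lower iron uptake response. Of 16 tested genes of iron uptake and transport, a list written after the fallen genes were seen and so no independent evidence, 7 fell and 1 rose in severe drought (list median -2.78, camera p = 1.7e-09, and p = 0.0025 with an estimated correlation, neither adjusted). Loci of that list without a matching symbol in the reference were left out, so its results do not cover them. Among them were IRO2, TOM1, DMAS1, HRZ1, HRZ2, FER1, FER2 and LOC_Os12g18410.MSUv7.0, which was listed as MIR. NRAMP1, a metal transporter, went from 1090 ± 284 to 7.3 ± 9.03 CPM (-7.23 ± 1.04), and IRO3, a transcription factor of the iron response, from 273 ± 82.8 to 17.8 ± 11.6 (-3.94 ± 0.59). NAAT1, of phytosiderophore synthesis, changed by -5.60 ± 0.59, YSL2 by -5.57 ± 0.99, and IRT2 had 1 count in severe drought, a ratio of 1450 (95% counting interval 260 to 57300; 901 without severe drought replicate 2, and at least 339-fold lower without replicate 1). In mild drought 4 fell and 1 rose (10 and 2 when adjusted over the list alone; camera p = 1.4e-05, and p = 0.0076 with an estimated correlation, neither adjusted), with NAAT1 at -2.73 ± 0.51 and YSL2 at -5.29 ± 0.98. Between severe and mild drought 0 passed over all genes and 4 were lower when adjusted over the list alone (list median -0.07, camera p = 4.3e-05, and p = 0.013 with an estimated correlation, neither adjusted), with NRAMP1 at -4.44 ± 0.92, NAAT1 at -2.86 ± 0.53 and IRO3 at -2.51 ± 0.55. The 4 that fell in mild drought became 2 without wet control replicate 3, and 1 and 2 without mild drought replicates 1 and 2. After 30 min of heat 2 rose and 1 fell (0 and 7 with total counts only). After 60 min 6 fell and 0 rose (list median -0.72), among them NAS2 (-2.77 ± 0.94), NAAT1 (-1.69 ± 0.49) and VIT1, a vacuolar iron transporter (-1.31 ± 0.30). The camera test of the 16 genes was not past the threshold at either time of heat, even without adjustment. The 6 became 3 without wet control replicate 3, and 3, 2 and 2 without 60 min replicates 1, 2 and 3.

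Root tissue in the wet control libraries is a technical explanation for the iron genes. It would lower other root genes too: LSI1 stood at 0.47 ± 0.27 and AMT1;3 at 0.50 ± 0.31 in severe drought, and the metal transporters IRT1 and NRAMP5 at -1.05 ± 0.51 and -1.63 ± 0.91. It stays open, since LSI1 had 22.4 ± 7.08 CPM in the drought shoots themselves, a level that would hide a small share of root. A small share would have to account for 1090 ± 284 CPM of NRAMP1 and 273 ± 82.8 CPM of IRO3 in the wet control. Levels in root were not measured, so these values do not decide it. Root tissue would have to be in the heat libraries of wet pots too, where NRAMP1 had 1390 ± 675 CPM at 30 min and 1640 ± 280 at 60 min. NAS1 had 11.6 ± 6.76 and 9.14 ± 2.69 CPM there, below the wet control and above both droughts. A lower iron uptake response in drought shoots may be a biological explanation: the higher of IRO3 and YSL15 was -3.94, but YSL15 (-4.44, adjusted p = 0.24, edgeR) was not past the threshold. That stays open too, and reads shared between NAS1 and NAS2 were not tested.

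Libraries of 1 group differed along an axis. Depth was argued against, since the library furthest along the axis had the most counts in 1 of 5 groups and the fewest in 1 other. Collection at another time of day predicts opposite slopes for PRR1 and LHY, a dusk and a dawn gene, and both fell along it (-0.13 ± 0.05 and -0.19 ± 0.05 log2 per SD). A larger share of growing tissue may contribute: 9 of 12 cell division genes and 9 of 9 expansins had slopes above 0, but other differences between shoots would do the same, so it stays open. No biological explanation given by the design was tested.

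After 30 min of heat the median log2 fold change was -1.02 by total counts and -0.14 with TMM factors, a shift of -0.88. Counts taken by strongly induced genes could lower all others: with the 335 genes at least 16-fold higher, which held 28.4 to 32% of the counts at 30 min, left out of the totals, the shift was -0.37, between the sizes set beforehand for and against this explanation, which stays open for the rest of the shift. Less mRNA of most genes per plant stays open, since counts hold no absolute scale: with those genes left out, the 9 pairs of libraries gave medians from -0.71 to -0.09.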
